A study of Mus musculus with 24 samples.

How the data were processed

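RNA abundance was measured by sequencing of the kidney inner medulla of C57BL/6 mice aged 9 to 10 weeks. Per the labels, each mouse received a single intraperitoneal injection (100 µl) of saline or of cisplatin at 15 mg/kg, and the inner medulla was snap frozen 72 h later. The labels name an RNA kit of Zymo, selection of poly(A) RNA, and library preparation and sequencing by a service provider. The values used were the counts that the authors deposited, whole numbers of sequenced fragments or reads per gene and library, under Ensembl gene identifiers. The submitters' processing notes name Trim Galore 0.6.7 (adapter and quality trimming), Subread 2.0.1 with featureCounts (counting of reads in genes), DESeq2 1.28.1 and the mouse genome build mm10, without roles or order. The aligner, the annotation release and the strand setting are not given in the sources used here. Of 55416 gene identifiers, 2147 begin with ENSMUSG00002 and 0 of these were in the reference annotation at hand. Genes are therefore given by symbol, identifier and chromosome and without coordinates, symbols came from a reference table of gene names, and chromosomes and the genomic spans of genes from that annotation. A symbol was found for 52083 identifiers, the other 3333 held 0.24% of the counts, and 67 symbols belonged to more than 1 identifier. All libraries had 0 counts for 13952 identifiers.

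The 24 libraries were grouped by the labels as male saline (6), male cisplatin (6), female saline (7) and female cisplatin (5). The labels do not state that each library came from a single mouse, and the p-values measure the spread between libraries. Total counts per library had a mean (in units of 1000000) of 22.2 ± 2.71 in male saline (SD, n = 6), 23.0 ± 3.31 in male cisplatin (n = 6), 23.3 ± 2.88 in female saline (n = 7) and 21.8 ± 2.12 in female cisplatin (n = 5). Replicate numbers carry no pairing: the correlation of centred log values between libraries of the same number in 2 groups had medians of -0.01, -0.1, -0.031 and -0.219 over the 4 pairs of groups. No library was a copy of another in its group, since the chi-square per gene between libraries of a group was at least 8.73 over 61 pairs. Pairs across groups were not compared in this way. Sex was checked with Xist and 4 Y-linked genes, and every library matched its label.

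Differences were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM factors, and a quasi-likelihood model with a mean per group was fitted to all 24 libraries. The negative binomial dispersions, estimated before that fit, had a common biological coefficient of variation of 0.251 and prior degrees of freedom of 4.52. Of the identifiers, 18005 were tested. The contrasts were cisplatin against saline in males and in females, the difference of these (the interaction of sex and treatment), and female against male under saline and under cisplatin. Benjamini-Hochberg adjusted p under 0.05 counted as changed. Levels are CPM with TMM-scaled library sizes, and errors are SD between libraries or SE of a log2 fold change. Overlap of the male and female gene sets was tested with Fisher's exact test per direction. Principal components were computed from log2 CPM of the 500 most variable tested genes.

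Gene lists were written from general knowledge before the data were examined, as were the contrasts, tests, alternatives and the rule for named genes. They covered injury and stress (tubular injury and repair, p53 targets, DNA repair, cell cycle, regulated cell death, antioxidant response, endoplasmic reticulum stress), inflammation (inflammatory cytokines and NF-kB, interferon response, complement and acute phase), and markers of macrophages and monocytes, neutrophils, lymphocytes, principal cells, intercalated cells, thin limbs, smooth muscle, endothelium, urothelium, proximal tubule, thick ascending limb, distal convoluted and connecting tubule, podocytes, adipocytes and erythroid cells. They also covered osmoprotection and NFAT5 targets, endothelin, nitric oxide and prostaglandin signalling, histone deacetylases and sirtuins, fibroblast and extracellular matrix, simple epithelial keratins, immediate early genes, the circadian clock, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, platinum transport and handling, steroid hormone receptors, male-high and female-high kidney genes, Y-linked genes, and X-linked genes that escape inactivation. The X-linked list also held Xist, the X-inactivation transcript. Each list with at least 3 tested members was tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists tested per contrast. The neutrophil list had 1 tested member and the adipocyte list too few, so neither had a set test, and the neutrophil member did not pass in males (log2 fold change -0.20) or females (0.07). The counts of members past the threshold are given over all genes and adjusted over the list alone. With a correlation estimated per list, 1 of 11 calls held in males, 1 of 10 in females, 0 of 14 in the interaction, 4 of 10 under saline and 3 of 11 under cisplatin.

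Named genes followed a rule. Per contrast it took the 10 raised and 10 lowered genes with the largest absolute log2 fold change among those past the threshold with a mean of at least 1 CPM in a compared group, leaving out predicted genes. From each list described it took the 3 tested members with the smallest p and the member with the highest mean level. In the sex contrasts it took all Y-linked and X-linked list members, and in the cisplatin contrasts Havcr1, Lcn2, Cdkn1a and Aqp2. Which lists to describe was chosen after their values were seen, and any other named gene is given as chosen after its values were seen. Some genes that the rule takes are not reported here.

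The analysis was tested on simulated data of the same size with 200 changed genes. Of genes changed 2-fold, 63.6% were recovered for the male contrast, 64.2% for the female contrast, 43.9% for the interaction, 65.7% for sex under saline and 67.7% for sex under cisplatin. Of genes changed 4-fold the shares were 93.8%, 89.4%, 82.8%, 87.9% and 89.4%, and of genes changed 1.5-fold 29.9%, 35.8%, 6.1%, 26.6% and 34.3%. False calls numbered 3, 5, 2, 7 and 5. The simulation drew genes independently and gave each gene the same spread in all groups. In the data the median SD of log2 CPM was 0.409 in male cisplatin and 0.201 in male saline libraries. The shares and false calls therefore describe that simpler setting and do not carry over directly to the real contrasts.

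Alternatives to the settings were DESeq2 size factors or total counts in place of TMM, no filter (a count in at least 1 library) or CPM of at least 1 in at least 5 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, the replicate number as a block, a tubule marker score (the mean of the proximal tubule and thick ascending limb list scores) as a covariate, only the groups compared, and each library left out in turn. Set tests were also run with an estimated correlation and with fry. Leaving out male cisplatin 5, female saline 1 and female saline 6 together was added after the data were seen. Male cisplatin 5 had 2.29% mitochondrial counts (4.12% to 6.63% in the other 5 of its group) and 5.73% ribosomal protein counts. Female saline 1 had a list score, the mean log2 CPM of the members, of 2.90 for lymphocytes (others 1.17 to 1.44) and 2.75 for the cell cycle (others 1.60 to 2.16). Female saline 6 had 2.85% mitochondrial counts (others 3.87% to 6.38%) and a thick ascending limb score of 6.66 (others 7.63 to 9.06). Male saline 2 was kept in that alternative. It had 3.52% mitochondrial counts (others of its group 4.92% to 6.55%) and a thick ascending limb score of 7.49 (others 8.60 to 9.20). Each count of genes was also set against 99 other splits of the libraries into groups of the same sizes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and plots. All 24 libraries were used, and sequence reads were not analysed here.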

Results

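Poly(A)-selected RNA from the kidney inner medulla of C57BL/6 mice, a common inbred laboratory strain, was sequenced 72 h after a single intraperitoneal injection of saline or of cisplatin at 15 mg/kg. Cisplatin is a platinum drug used against tumours that binds DNA and injures kidney tubules. The inner medulla is the innermost zone of the kidney and holds collecting ducts, thin limbs, interstitial cells and capillaries. The comparisons address how its transcripts differ after cisplatin-induced acute kidney injury in males and in females. The 24 libraries comprised 6 from male saline, 6 from male cisplatin, 7 from female saline and 5 from female cisplatin animals. Total counts per library (in units of 1000000 counts) ranged from 18.1 to 27.3 with a mean of 22.6 ± 2.70 (SD, n = 24). Of the 55416 gene identifiers, 18005 had enough counts to be tested. In a principal component analysis of the 500 most variable genes, the first component held 44.1% of the variance. The 13 saline libraries lay between -17.2 and -10.2 on it, the 6 male cisplatin libraries between -4.2 and 42.9, and the 5 female cisplatin libraries between -7.8 and 34.2. The second component (15.9% of the variance) separated the sexes, with male libraries from 2.78 to 18.0 and female libraries from -16.0 to -5.63. Ribosomal protein genes took 2.25% ± 0.0454 of the counts in male saline (SD, n = 6), 3.30% ± 1.23 in male cisplatin (n = 6), 2.37% ± 0.200 in female saline (n = 7) and 3.05% ± 0.668 in female cisplatin libraries (n = 5).

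In males, Lcn2 (ENSMUSG00000026822, chromosome 2), which encodes an iron-siderophore carrier released by injured tubules, rose from 63.3 ± 4.20 counts per 1000000 (CPM) under saline to 2856 ± 2238 CPM under cisplatin (SD, n = 6 each). Its log2 fold change was 5.50 ± 0.77 (SE), with an adjusted p of 0.000117 from edgeR's quasi-likelihood test. Spp1, which encodes the matrix protein osteopontin, rose from 1548 ± 121 to 7935 ± 5375 CPM. The epithelial calcium channel gene Trpv6 (ENSMUSG00000029868, chromosome 6) rose from 3.43 ± 0.836 to 65.5 ± 30.2 CPM, a log2 fold change of 4.25 ± 0.32 with an adjusted p of 8.61e-09. The adjacent Trpv5 rose by 5.30 ± 0.68 on the log2 scale. Kel, a neighbour of both that encodes a metalloendopeptidase of the red cell surface, rose by 4.82 ± 0.74. Whether reads were assigned by strand is not given in the sources used here. The largest falls were in hemoglobin genes. Hbb-bs (ENSMUSG00000052305, chromosome 7) fell from 114 ± 39.5 to 3.10 ± 1.45 CPM, with a log2 fold change of -5.21 ± 0.37 and an adjusted p of 4.19e-09. Among other falls were Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis (-2.70 ± 0.46), and Hgf, hepatocyte growth factor (-2.16 ± 0.38). In edgeR's test 3731 of the 18005 genes changed at an adjusted p under 0.05. Of these, 2374 were higher and 1357 lower under cisplatin, 752 and 397 of them by at least 2-fold. With a score of proximal tubule and thick ascending limb markers (the tubule marker score) as a covariate, 1563 genes passed, 1409 of them among the 3731, and with the male libraries fitted alone, 2402.

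**Figure D1:**
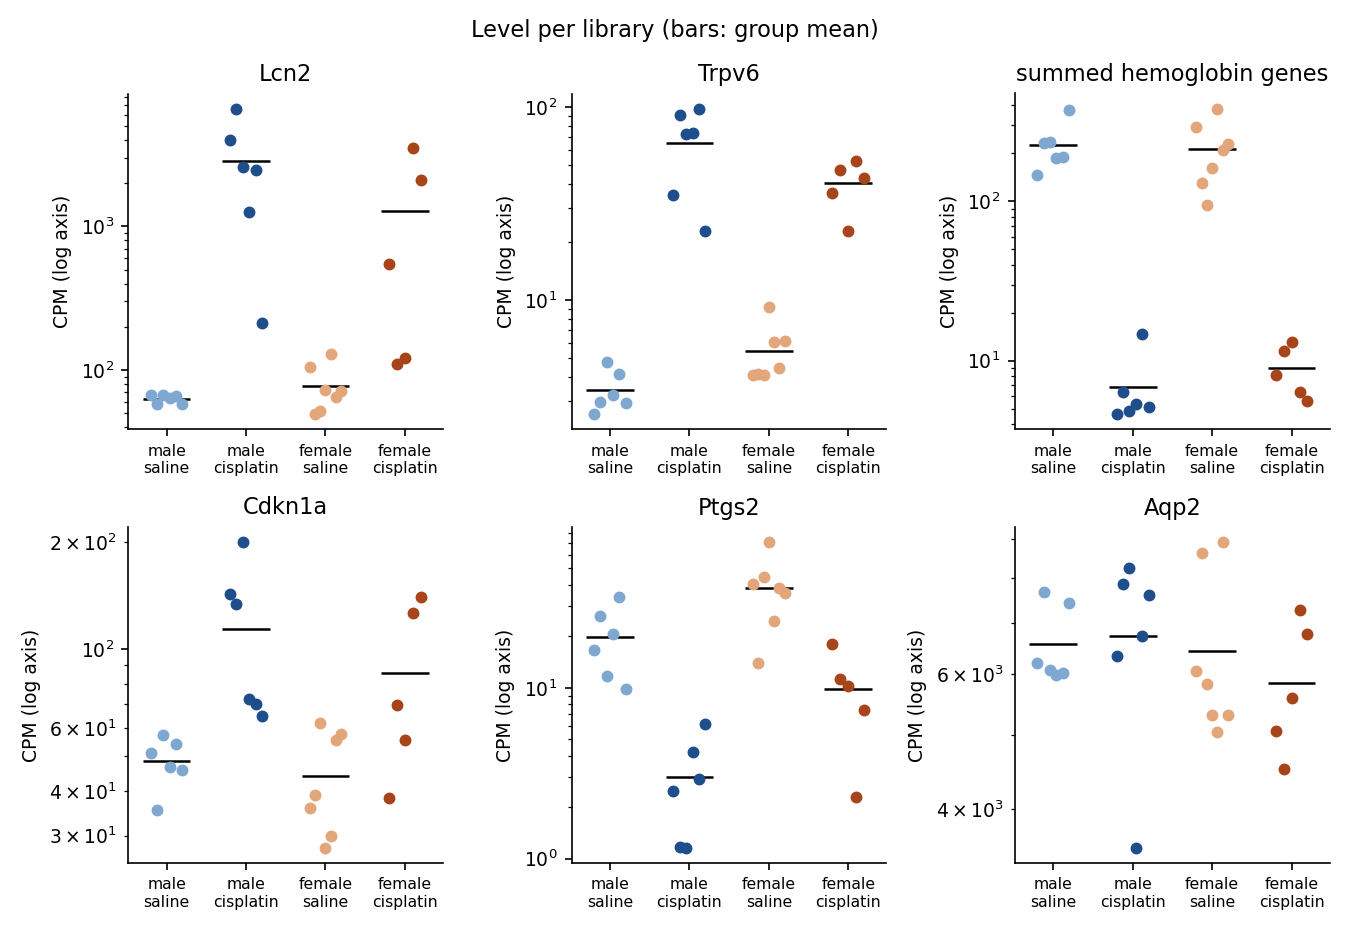
Counts per 1000000 (CPM, log axis) of Lcn2, Trpv6, the 4 hemoglobin genes summed, Cdkn1a, Ptgs2 and Aqp2 in each of the 24 libraries, with 1 point per library and a bar at each group's mean. The summed hemoglobin level was at most 14.7 CPM in every cisplatin library and at least 95.4 CPM in every saline library, and Trpv6 was at least 22.7 CPM in each cisplatin library against at most 9.18 CPM in the saline libraries.

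The genes of tubular injury and repair stood out in males. Of 16 tested members 12 rose and 0 fell at an adjusted p under 0.05, and 14 rose when adjusted over the list alone. Besides Lcn2 and Spp1 these included Lgals3, which encodes the lectin galectin-3 (1.05 ± 0.18), and the secreted chaperone Clu (2.37 ± 0.43). The list score, the mean log2 CPM of the members in a library, was 4.22 to 5.68 in male cisplatin 1 to 5 and 3.21 in male cisplatin 6, below the 3.25 to 3.48 of the 6 male saline libraries. The camera set test with its preset correlation gave an adjusted p of 3.1e-07 for this list, and the adjusted p = 0.454 with an estimated correlation. Of 17 tested interferon response genes 13 rose and 0 fell, and 15 rose when adjusted over the list alone. Oasl2, an interferon-induced antiviral protein gene, rose by 2.23 ± 0.40, the transcription factor gene Irf7 by 1.96 ± 0.35 and Ifit1 by 2.02 ± 0.37 on the log2 scale. The interferon list score was 4.42 to 6.00 in male cisplatin 1 to 5 and 3.69 in male cisplatin 6, against 3.35 to 3.88 under saline. That list had an adjusted p of 3.55e-09 (adjusted p = 0.454 with an estimated correlation). Oas2, an interferon-induced enzyme gene outside the list, rose from 5.92 ± 0.96 to 118 ± 87.4 CPM. Of 25 tested p53 targets 8 rose and 1 fell (12 and 1 when adjusted over the list alone). Among them were Gdf15, a stress-induced cytokine gene, at 2.77 ± 0.58 and Bax, a pro-apoptotic gene, at 0.75 ± 0.15. The list's adjusted p was 0.00578 (adjusted p = 0.489 with an estimated correlation). Cdkn1a, the p53-induced cyclin-dependent kinase inhibitor gene, rose from 48.5 ± 7.81 to 114 ± 54.0 CPM (1.23 ± 0.30, adjusted p of 0.00791). Of 18 tested antioxidant response genes 8 rose and 1 fell (11 and 1 when adjusted over the list alone), among them the thioredoxin gene Txn1 (0.52 ± 0.12). The list's adjusted p was 0.0186 (adjusted p = 0.489 with an estimated correlation). Of 6 tested simple epithelial keratins 3 rose, and 5 when adjusted over the list alone, with an adjusted p of 0.0432 for the list (adjusted p = 0.489 with an estimated correlation). In single libraries, the antioxidant score of male cisplatin 4 and 6 (5.50 and 5.43) lay within the range of the male saline libraries (5.24 to 5.62), and so did their keratin score (7.48 and 7.49). With the tubule marker score as a covariate the adjusted p was 0.207 for the p53 targets (range over the alternatives 0.000438 to 0.489), 0.227 for the antioxidant genes (range 0.00402 to 0.489), 0.237 for the keratins (range 0.00904 to 0.489) and 0.0724 for Cdkn1a (range 0.000889 to 0.0724). Without male cisplatin 1 it was 0.0665 for the antioxidant genes and 0.0816 for the keratins. The keratins also missed the threshold without male saline 1 (0.0607), male saline 5 (0.0546), male saline 6 (0.0523) or male cisplatin 5 (0.0622). They missed it as well (0.068) when male cisplatin 5, female saline 1 and female saline 6, the 3 libraries of divergent composition, were left out together, a choice made after the data were seen.

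All 5 erythroid markers fell in males. The log2 fold changes of the hemoglobin genes Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 were -5.36, -5.21, -4.98 and -4.33. That of Alas2, the erythroid enzyme gene that starts heme synthesis, was -3.92 ± 0.48. The list's adjusted p was 1.04e-29, and 6.24e-04 with an estimated correlation. The paired hemoglobin copies are nearly identical in sequence, so the division of reads between them is uncertain. Fibroblast and extracellular matrix genes followed: 7 of 19 fell and 1 rose (9 and 1 when adjusted over the list alone). Those that fell included Pdgfra, a platelet-derived growth factor receptor gene of fibroblasts (-1.38 ± 0.32), and the collagen gene Col3a1 (-1.84 ± 0.44). The member that rose was Ccn2, a matricellular growth factor gene (1.72 ± 0.43). That list had an adjusted p of 6.06e-04 (adjusted p = 0.454 with an estimated correlation). Of 11 endothelial markers 5 fell and 1 rose (8 and 2 when adjusted over the list alone), with the angiopoietin receptor gene Tek at -0.78 ± 0.21. The adjusted p was 0.00744 (adjusted p = 0.489 with an estimated correlation). Of 14 osmoprotection genes and targets of NFAT5, the transcription factor of the response to hypertonicity, 3 fell and 0 rose (9 and 0 when adjusted over the list alone). Among them Hspa4l, a heat shock family gene induced by hypertonicity, fell from 281 ± 38.5 to 111 ± 79.4 CPM. The list's adjusted p was 0.00501 (adjusted p = 0.454 with an estimated correlation). The endothelial score was 6.13 to 7.20 in male cisplatin 1 to 5 and 7.57 in male cisplatin 6, above the 7.33 to 7.46 of the 6 male saline libraries. The osmoprotection score was 6.30 to 7.12 in male cisplatin 1 to 5 and 7.25 in male cisplatin 6, within the range of the saline libraries, whose lowest was 7.24. The matrix score of male cisplatin 4 (4.66) and the intercalated scores of male cisplatin 3 (5.05) and male cisplatin 4 (4.44) also lay within the saline ranges (4.54 to 4.96 and 4.25 to 5.07). Of 7 steroid hormone receptor genes 3 fell (5 when adjusted over the list alone), including the glucocorticoid receptor gene Nr3c1 (-0.74 ± 0.14). The adjusted p was 0.00546 (adjusted p = 0.157 with an estimated correlation). Of 12 markers of intercalated cells, the acid-base transporting cells of the collecting duct, 3 fell (4 when adjusted over the list alone). They included the receptor gene Insrr (-1.94 ± 0.37) and the anion exchanger gene Slc4a1 (-1.45 ± 0.33), and the adjusted p was 0.0213 (adjusted p = 0.645 with an estimated correlation). Markers of segments outside the inner medulla were measured beside these groups. Of 16 proximal tubule markers 0 passed in either direction (median log2 fold change -0.50, adjusted p of 0.0504 for the list), and 1 of 6 thick ascending limb markers fell (median -0.86, adjusted p of 0.139). The member that fell was Egf, epidermal growth factor, from 1104 ± 517 to 259 ± 196 CPM (adjusted p of 0.0182). Umod, a highly abundant transcript of that segment, had a log2 fold change of -1.10 ± 0.51 (adjusted p of 0.122). With the score of both marker lists as a covariate the adjusted p was 0.0522 for the steroid receptors (range over the alternatives 0.00012 to 0.157) and 0.458 for the intercalated markers (range 0.000505 to 0.645). For single genes it was 0.0789 for Egf (range 0.00372 to 0.0789), 0.11 for Ccn2 (range 0.00116 to 0.11) and 0.0769 for Tek (range 0.000608 to 0.0769). Egf is itself a member of this score, so its lost call with the covariate says little. For the intercalated markers the adjusted p was 0.073 without male cisplatin 1 and 0.101 without male cisplatin 6. The proximal tubule list itself passed without male saline 2 (0.0434), male saline 4 (0.033), male saline 5 (0.00498), male saline 6 (0.0308), male cisplatin 3 (0.0357), male cisplatin 4 (0.00479) or male cisplatin 5 (0.0106), with no filter (0.00424) and without the 3 libraries of divergent composition (0.00816, range over the alternatives 0.00424 to 0.788). The thick ascending limb list passed without male saline 2 (0.0406) and with no filter (0.0423, range 0.0406 to 0.852).

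**Figure D2:**
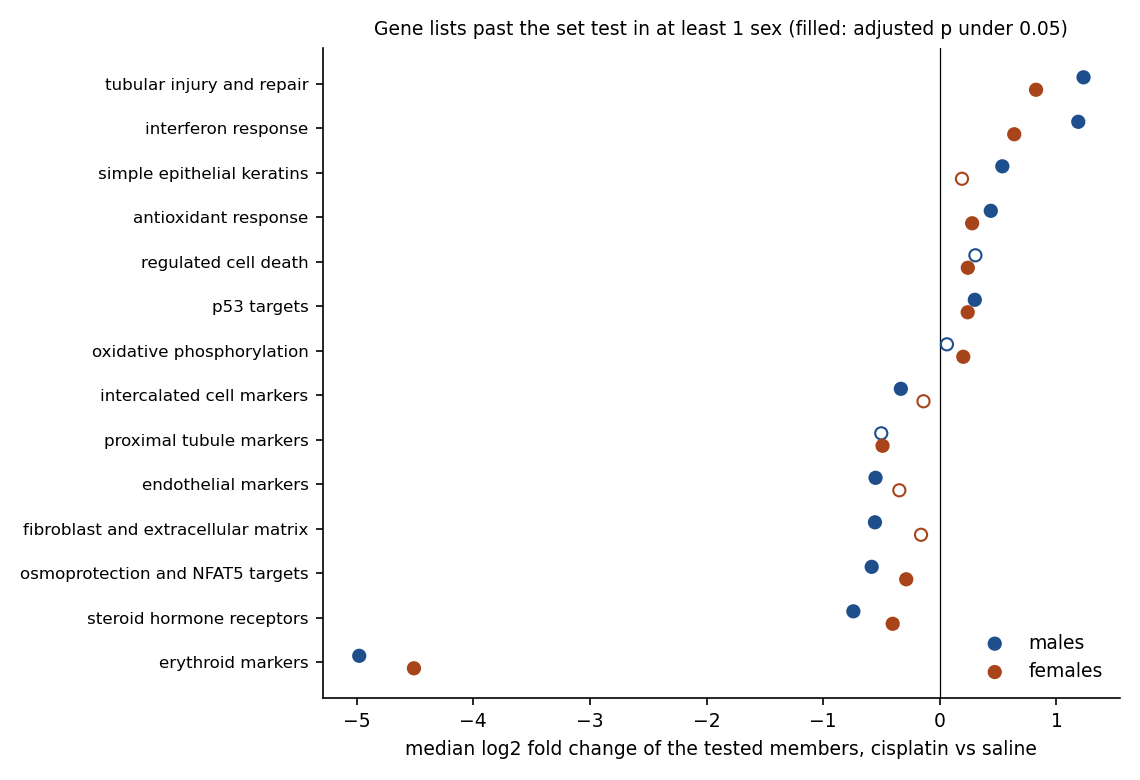
Median log2 fold change (cisplatin against saline) of the tested members of the 14 gene lists that passed the camera test with its preset correlation in at least 1 sex, in males (blue) and females (orange), with filled points where the adjusted p was under 0.05. Erythroid markers had medians of -4.98 in males and -4.51 in females, and this list alone also passed with an estimated correlation, in both sexes.

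Aqp2, the vasopressin-regulated water channel gene of principal cells, was at 6558 ± 770 CPM under saline and 6718 ± 1702 CPM under cisplatin in males (0.04 ± 0.19, adjusted p of 0.912). Of 15 principal cell markers 1 rose, the sodium channel subunit gene Scnn1b (1.84 ± 0.33), and 3 fell, with an adjusted p of 0.493 for the list. The regulated cell death list missed the threshold (adjusted p of 0.051), although 8 of 18 members rose and 1 fell, and the necroptosis genes Ripk3 (1.63 ± 0.32) and Mlkl (1.41 ± 0.30) were among those that rose. Of 17 cytokine and NF-kB genes 4 rose, including Csf1 (1.32 ± 0.23) and Cxcl10 (1.51 ± 0.32), and 4 fell (adjusted p of 0.794). Of 14 complement and acute phase genes 3 rose, among them the complement-inactivating protease gene Cfi (4.10 ± 0.46). Another 3 fell, and the adjusted p was 0.556. Of 13 macrophage and monocyte markers Cd14 (2.19 ± 0.30), part of the lipopolysaccharide receptor, and the lysosomal gene Cd68 (1.91 ± 0.37) rose. Adgre1 (-1.50 ± 0.44), a macrophage surface receptor gene, was among 2 that fell (adjusted p of 0.329 for the list). Of 16 endothelin, nitric oxide and prostaglandin genes 5 fell, including Ptgs2, and 1 rose, the endothelin gene Edn1 (1.86 ± 0.28), with an adjusted p of 0.0779. Of 6 distal convoluted and connecting tubule markers 3 rose, including Trpv5 and the magnesium channel gene Trpm6 (0.86 ± 0.18), and 2 fell (adjusted p of 0.556). Few or no members passed in the other cell type lists, whose adjusted p was 0.836 for lymphocytes (0 of 5) and 0.431 for thin limbs (1 of 7, lower). It was 0.0612 for smooth muscle (2 of 4, lower), 0.0913 for urothelium (2 of 10, higher) and 0.198 for podocytes (1 of 5, lower). Among process lists it was 0.5 for DNA repair (1 of 23, higher), 0.298 for the cell cycle (1 of 21, lower) and 0.974 for endoplasmic reticulum stress (5 of 15 higher, 4 lower). It was 0.411 for histone deacetylases and sirtuins (4 of 14 higher, 1 lower) and 0.431 for immediate early genes (2 of 9, higher). It was 0.479 for the circadian clock (0 of 14), 0.463 for fatty acid oxidation (1 of 14 higher, 2 lower) and 0.77 for oxidative phosphorylation (1 of 15, lower). It was 0.884 for glycolysis and hypoxia (3 of 18, higher) and 0.463 for platinum transport and handling (2 of 11, higher). Male-high kidney genes (0 of 8) had an adjusted p of 0.0501 and female-high kidney genes (1 of 4, higher) 0.556. Y-linked genes (0 of 4) had 0.947 and X-linked genes that escape inactivation (1 of 5 higher, 2 lower) 0.572. Of the members of the X-linked list only Xist, at a low level in males, had a higher mean under cisplatin (3.87 CPM against 1.49 CPM). The median, mean and test of a list differed in sign for 7 of 39 tested lists in males, 8 in females, 9 in the interaction and 4 and 5 between the sexes under saline and cisplatin, and 0 of these passed. Adgre1 had an adjusted p of 0.0205, which was 0.119 with the tubule marker score as a covariate (range over the alternatives 0.00428 to 0.119). The regulated cell death list passed in 10 of 22 alternatives (range 0.0173 to 0.489), among them those without male saline 4 (0.0386), male saline 6 (0.0308), male cisplatin 4 (0.0338), male cisplatin 5 (0.0265) or male cisplatin 6 (0.0351). The endothelin list passed in 4 of 22 (range 0.00789 to 0.489), among them that without male cisplatin 4 (0.0403), and the macrophage list passed with no filter (0.0423, range 0.0423 to 0.788). Havcr1, the kidney injury molecule 1 gene, had too few counts to be tested, with a mean of 0.792 ± 0.873 CPM in male cisplatin libraries (n = 6) and 0.0944 ± 0.105 CPM in male saline libraries (n = 6).

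In females, the calcium channel genes rose after cisplatin. Trpv6 went from 5.46 ± 1.88 CPM (SD, n = 7) to 40.2 ± 11.4 CPM (SD, n = 5) with a log2 fold change of 2.88 ± 0.29 (SE) and an adjusted p of 2.11e-06. Trpv5 rose by 4.37 ± 0.61 (adjusted p of 4.14e-04). Lcn2 rose from 77.8 ± 29.0 to 1281 ± 1498 CPM (4.04 ± 0.68, adjusted p of 0.00438). Its values in the 5 cisplatin libraries ran from 111 to 3529 CPM against 49.4 to 129 CPM in the saline libraries. Oas2 rose by 3.08 ± 0.54 and Cfi by 2.80 ± 0.42. Further raised genes were Socs3, an inhibitor of cytokine signalling (2.65 ± 0.46, adjusted p of 0.00571), and Adgra1, an adhesion receptor gene (2.67 ± 0.47, adjusted p of 0.00571). All 5 erythroid markers fell, with Hbb-bs going from 108 ± 48.1 to 4.25 ± 1.93 CPM (adjusted p of 9.85e-08). The list's adjusted p was 2.95e-50, and 1.32e-05 with an estimated correlation. Among other genes that fell were Dpyd, an enzyme of pyrimidine breakdown (-2.03 ± 0.38, adjusted p of 0.0125), and Fhit, a dinucleoside hydrolase gene (-2.31 ± 0.46, adjusted p of 0.0253). In edgeR's test 49 of 18005 genes changed, 36 higher and 13 lower, and 33 and 9 of these by at least 2-fold. That count was 241 with DESeq2 and 85 with no filter on low counts. It was 32 without the 3 libraries of divergent composition, 28 with the tubule marker score as a covariate, 20 with female libraries fitted alone and 12 with limma-voom. It was 32, 31, 29, 27 and 31 without female saline 1 to 5 in turn, and 101, 100, 139, 21 and 21 without female cisplatin 1 to 5.

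Of the injury and repair genes, 2 of 16 rose in females, Lcn2 and Spp1, and 5 rose when adjusted over the list alone. The list score was 5.59 and 4.71 in female cisplatin 4 and 5, while it was 3.77, 3.71 and 3.77 in female cisplatin 1, 2 and 3, within the 3.37 to 3.88 of the 7 female saline libraries. The list had an adjusted p of 7.68e-05 (adjusted p = 0.531 with an estimated correlation). Spp1 went from 1684 ± 224 to 5209 ± 3105 CPM (1.63 ± 0.36, adjusted p of 0.0473), and in 15 of 22 alternatives its adjusted p was not under 0.05 (range 0.00182 to 0.35). The interferon list score was 4.21, 3.99, 4.75, 5.32 and 4.76 in female cisplatin 1 to 5 and 3.59 to 4.30 under saline. Interferon response genes had 0 of 17 members past the threshold over all genes and 9 higher when adjusted over the list alone, with an adjusted p of 2.1e-05 for the list (adjusted p = 0.531 with an estimated correlation). Isg15, the ubiquitin-like interferon-induced protein gene, had a log2 fold change of 1.77 ± 0.51 (adjusted p of 0.142). For 25 p53 targets the counts were 0 over all genes and 6 higher when adjusted over the list alone (adjusted p of 0.00289 for the list, adjusted p = 0.531 with an estimated correlation). Cdkn1a was at 44.0 ± 14.2 CPM under saline and 86.0 ± 44.8 CPM under cisplatin (adjusted p of 0.171). For 18 antioxidant genes the counts were 0 and 2 higher (adjusted p of 0.00655, adjusted p = 0.531 with an estimated correlation). The metallothionein gene Mt2 had a log2 fold change of 3.97 ± 1.06 (adjusted p of 0.116). In female cisplatin 1 to 5 the p53 score was 4.56, 4.81, 4.47, 5.24 and 5.202 (4.36 to 4.79 under saline) and the antioxidant score 5.39, 5.60, 5.04, 6.35 and 6.30 (5.06 to 5.58 under saline). The osmoprotection score was 7.63, 7.36, 7.30, 6.39 and 6.80 (7.42 to 7.65 under saline) and the steroid receptor score 2.80, 2.93, 3.02, 2.51 and 2.41 (2.70 to 3.48 under saline). Among lists shifted down, the 14 osmoprotection genes had 0 members past the threshold by either adjustment (adjusted p of 0.00179, adjusted p = 0.531 with an estimated correlation). The 7 steroid receptors had 0, and 3 lower when adjusted over the list alone (adjusted p of 0.00453, adjusted p = 0.143 with an estimated correlation). Proximal tubule markers, which stand for tissue outside the inner medulla, had 0 of 16 members past the threshold, a median of -0.49 and an adjusted p of 0.00857 (adjusted p = 0.739 with an estimated correlation). The thick ascending limb markers had a median of -0.16 and an adjusted p of 0.765. The regulated cell death (0 of 18) and oxidative phosphorylation (0 of 15) lists were shifted up with adjusted p of 0.0426 and 0.0441 (adjusted p = 0.531 and adjusted p = 0.739 with an estimated correlation). In these lists and the proximal tubule list 0 members passed when adjusted over the list alone. The other 29 tested lists had adjusted p from 0.0596 to 0.969. Aqp2 was at 6436 ± 1624 CPM under saline and 5832 ± 1152 CPM under cisplatin (adjusted p of 0.752). With the tubule marker score as a covariate the adjusted p was 0.0527 for the proximal tubule list (range over the alternatives 0.000316 to 0.739) and 0.0512 for the antioxidant list (range 0.000498 to 0.531). The proximal tubule list is part of that score, so its lost call with the covariate says little. With the same covariate the adjusted p was 0.0514 for Lcn2, which also missed the threshold with limma-voom (0.144) and with female libraries fitted alone (0.0524, range 2.16e-06 to 0.199). For the proximal tubule list the adjusted p was 0.0938 without female cisplatin 1 and 0.0802 without female cisplatin 5.

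Several of the female calls lay near the threshold and ended when a library was left out, while over all alternatives the log2 fold change stayed between 1.25 and 1.83 for Spp1, -2.56 and -2.11 for Fhit and -2.36 and -1.82 for Dpyd. The range was wider for Lcn2 (2.38 to 4.34), Oas2 (2.16 to 3.36), Adgra1 (1.74 to 2.93), Socs3 (1.83 to 2.99) and Cfi (2.19 to 3.02). The adjusted p of Spp1 without female saline 1 to 7 in turn was 0.115, 0.0805, 0.114, 0.0848, 0.0923, 0.0815 and 0.0883, and it was 0.35 without female cisplatin 4 and 0.218 without female cisplatin 5. Without female cisplatin 4, the adjusted p was 0.0581 for Adgra1 (range over the alternatives 4.96e-05 to 0.164), 0.0515 for Socs3 (range 4.96e-05 to 0.207) and 0.0624 for Dpyd (range 1.16e-05 to 0.0802). Without female cisplatin 5 it was 0.0802 for Dpyd and 0.126 for Fhit (range 7.64e-05 to 0.126), and for Fhit it was 0.0551 without female saline 2 and 0.0503 without female saline 4. For Oas2 the adjusted p was 0.182 with limma-voom and 0.0718 without the 3 libraries of divergent composition (range 2.01e-05 to 0.182), and for Cfi it was 0.112 with limma-voom (range 9.77e-09 to 0.112). With limma-voom and with female libraries fitted alone the adjusted p was 0.164 and 0.0697 for Adgra1 and 0.156 and 0.0718 for Socs3. Mt2 passed without female cisplatin 3 (0.0433) and with DESeq2 (0.0204, range 0.0204 to 0.689), and Scnn1b, at 1.22 ± 0.33 with an adjusted p of 0.116, with DESeq2 (0.0285).

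Whether males and females responded differently was tested by the interaction of sex and treatment. Lcn2, Trpv5, Trpv6, Oas2, Cfi and the 5 erythroid genes were among 46 genes that passed in both sexes, and all 46 moved in the same direction. The 35 shared raised genes compared with 4.75 for independent lists (Fisher's exact p of 4.03e-30, two-sided), and the 11 shared lowered genes with 0.98 (Fisher's exact p of 2.91e-11, two-sided). The male and female contrasts share no library, but both use the same spread per gene, estimated over all libraries. Fisher's test also treats genes as independent, which they are not, so its p does not measure the spread between libraries. The 3 genes that passed in females and not in males were Fhit (male adjusted p of 0.0642), Tes (0.0800) and Ifitm5 (0.989), of which Tes and Ifitm5 were singled out after their values were seen. Across all 18005 genes, which are not independent replicates, the log2 fold changes of the sexes correlated with Pearson's r of 0.729 and Spearman's rho of 0.691, and 76.9% had the same sign in both sexes (96.5% of the genes called in males, a selected set). Over the 4881 genes called in the contrast averaged over both sexes, the median absolute log2 fold change was 0.62 in males and 0.37 in females. In edgeR's interaction test 0 genes passed an adjusted p under 0.05 and 772 had an unadjusted p under 0.05. DESeq2 and limma-voom each also called 0. Ifit1 (-1.16 ± 0.51), Lgals3 (-0.66 ± 0.25) and Col1a1 (1.06 ± 0.49) had interaction log2 fold changes, female minus male, with adjusted p of 0.943 each. At the level of lists the interferon response (median -0.74, adjusted p of 1.83e-05) and the injury and repair genes (median -0.62, adjusted p of 3.33e-04) were shifted toward a smaller rise in females (for each, adjusted p = 0.721 with an estimated correlation). Part of these shifts lay between the saline libraries. There the interferon score was 3.59 to 4.30 in females and 3.35 to 3.88 in males, and the injury score 3.37 to 3.88 and 3.25 to 3.48. The cisplatin libraries of each sex differed widely in these lists: the injury score of female cisplatin 4 and 5 (5.59 and 4.71) lay within the 4.22 to 5.68 of male cisplatin 1 to 5, and that of female cisplatin 1 to 3 (3.71 to 3.77) and male cisplatin 6 (3.21) did not exceed the highest saline library of their sex (3.88 and 3.48). The matrix genes (median 0.44, adjusted p of 2.67e-04) were shifted toward a smaller fall (adjusted p = 0.721 with an estimated correlation). The number of shared genes was 194 with DESeq2 and 80 with no filter, under which the correlation was 0.175. It was 29 without the 3 libraries of divergent composition, 27 with the tubule marker score as a covariate, 18 with each sex fitted alone and 12 with limma-voom. Without single libraries the shared number was 111 (male cisplatin 6), 93, 88, 122, 19 and 21 (female cisplatin 1 to 5), 30, 30, 27, 26 and 29 (female saline 1 to 5) and 30 (female saline 7).

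**Figure D3:**
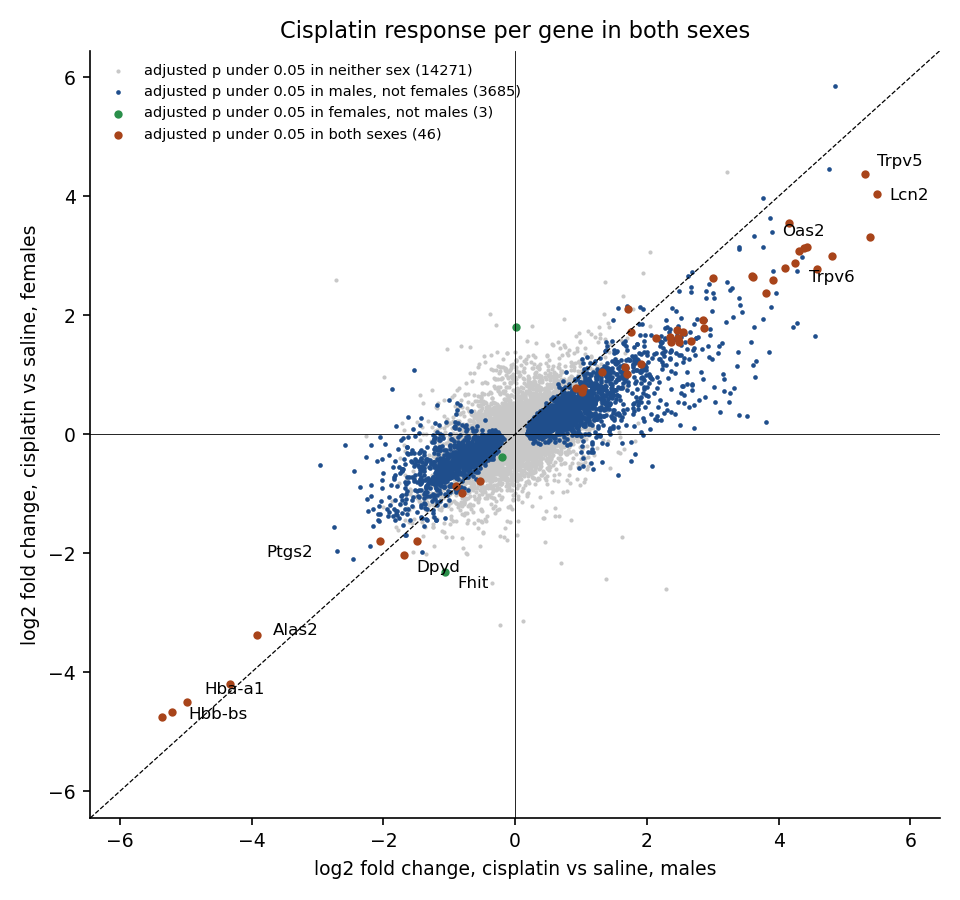
Log2 fold change (cisplatin against saline) of each of the 18005 tested genes in males (horizontal axis) and females (vertical axis), coloured by whether the adjusted p was under 0.05 in both sexes (46 genes), males and not females (3685), females and not males (3) or neither (14271), with the line of equal change dashed. The 5 erythroid genes lie at the lower left, close to that line, and Lcn2, Trpv5, Trpv6 and Oas2 at the upper right.

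Under saline, the sexes differed most in sex-linked transcripts and in a small group of kidney genes known to differ by sex. Xist (ENSMUSG00000086503), the X-inactivation transcript, was at 311 ± 45.1 CPM in females (SD, n = 7) and 1.49 ± 0.430 CPM in males (n = 6), a log2 fold change of 7.71 ± 0.23 with an adjusted p of 1.08e-17. The Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y were lower in females, with log2 fold changes of -5.63, -5.62, -5.58 and -5.58 (adjusted p = 2.21e-15 for the list with an estimated correlation). The list of X-linked genes that escape inactivation, which also holds Xist itself, had 4 of 5 members higher. Besides Xist these included Kdm6a, a histone demethylase gene (0.72 ± 0.13). With Xist included, the list had an adjusted p of 1.46e-102, and 2.13e-12 with an estimated correlation. Of the members, Ddx3x (0.57 ± 0.12, adjusted p of 0.0318) and Eif2s3x (0.53 ± 0.11, adjusted p of 0.0382) had log2 fold changes of 0.524 to 0.614 and 0.479 to 0.569 over the alternatives. Each lost the call in 14 of 23 alternatives (adjusted p ranges 0.000529 to 0.147 and 0.000112 to 0.123). Ddx3x lost it without any one of male saline 1 to 6 (0.0525 to 0.147) or female saline 1, 2, 4, 5, 6 and 7 (0.0661 to 0.0786). Eif2s3x lost it without any one of male saline 1 to 6 (0.067 to 0.123) or female saline 1, 3, 4, 6 and 7 (0.0591 to 0.105). The Y-linked genes summed to 1.06% to 3.38% of the male mean in the female saline libraries, so these fold changes are distances from that background. In each of the 24 libraries these transcripts matched the labelled sex, with Xist at 217 CPM or more in the female and 5.61 CPM or less in the male libraries. Of 8 male-high kidney genes 5 were lower in females, including the organic anion transporter gene Slco1a1 (-5.11 ± 0.82) and the cytochrome gene Cyp2e1 (-3.63 ± 0.60). The count was 6 lower when adjusted over the list alone (adjusted p of 7.72e-29, and 2.23e-05 with an estimated correlation). Of 4 female-high kidney genes 2 were higher, and all 4 when adjusted over the list alone. The amino acid transporter gene Slc7a12 was at 5.87 ± 0.75 (adjusted p of 1.79e-18 for the list, and 1.1e-04 with an estimated correlation). Outside the lists, the renin gene Ren1 was higher in females (2.47 ± 0.38, adjusted p of 0.00176), as was the glucuronosyltransferase gene Ugt1a2 (5.64 ± 0.66), which shares exons with its gene family so that its reads are uncertain. Acsm3, an acyl-CoA synthetase gene, was lower (-4.42 ± 0.57, adjusted p of 9.15e-05). Among female saline libraries, number 7 had the highest level of Acsm3 (2.00 CPM against 0.346 to 0.684 in the other 6) and of Slco1a1 (0.409 CPM), with a Y-linked sum of 3.31% of the male mean. Many of these sex-dependent genes are known from the proximal tubule, whose 16 markers had a median log2 difference of -0.24 and an adjusted p of 0.126. Across male saline 1 to 6 the male-high score was 4.31, 3.43, 4.39, 3.35, 2.37 and 3.49. The proximal tubule score was 4.23, 3.40, 4.37, 3.21, 2.25 and 3.15. Among female saline libraries both the female-high and the proximal tubule score were highest in number 4 and lowest in number 6. Whether these sex differences arise in inner medullary cells or in proximal tubule tissue within the samples was not tested. In edgeR's test 34 genes differed, 11 higher and 23 lower in females, and the count was 58 with DESeq2, 57 with limma-voom and 21 without male saline 3.

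Other lists passed the set test between the sexes under saline without any member past the threshold over all genes, and none of these calls held with an estimated correlation. Immediate early genes (0 of 9, and 3 higher in females when adjusted over the list alone) had an adjusted p of 8.06e-07 (adjusted p = 0.295 with an estimated correlation). The nuclear receptor gene Nr4a1, a member, was at 45.1 ± 29.3 CPM in females (SD, n = 7) and 15.4 ± 9.90 CPM in males (SD, n = 6), with an adjusted p of 0.41 in edgeR's test. Interferon response genes (0 of 17) were shifted up with an adjusted p of 1.83e-04 (adjusted p = 0.67 with an estimated correlation). Fatty acid oxidation (0 of 14), oxidative phosphorylation (0 of 15) and antioxidant genes (0 of 18) were shifted down with adjusted p of 2.37e-05, 2.72e-05 and 0.00361 (adjusted p = 0.51, adjusted p = 0.67 and adjusted p = 0.572 with an estimated correlation). In these 4 lists 0 members passed when adjusted over the list alone. The oxidative phosphorylation score was lowest in female saline 6, female saline 1 and male saline 2 (7.01, 7.15 and 7.24). These libraries also had the lowest thick ascending limb scores of the saline libraries (6.66, 7.63 and 7.49). The other saline libraries had at least 7.36 and 8.24. For the oxidative phosphorylation list no value with the tubule marker score is given here, so whether the share of tubule tissue accounts for the shift stays open. Platinum transport and handling genes (0 of 11, and 1 lower when adjusted over the list alone) had an adjusted p of 0.0456 (adjusted p = 0.295 with an estimated correlation), with the export pump gene Abcc2 at -1.49 ± 0.33 (adjusted p of 0.062). Abcc2 passed without male saline 5 (0.0124) or male saline 6 (0.0451), with no filter (0.0267) and with DESeq2 (0.00247, range over the alternatives 0.00247 to 0.278). For the platinum list the value was 0.0654, 0.072 and 0.174 without male saline 1 to 3 and 0.0713, 0.0904, 0.0503, 0.0693 and 0.0577 without female saline 2, 3, 4, 6 and 7. It was 0.0591 with the CPM filter, 0.0759 with saline libraries fitted alone and 0.0575 without the 3 libraries of divergent composition (range over the alternatives 0.00197 to 0.491). The other 29 tested lists had adjusted p from 0.0745 to 0.897.

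Under cisplatin, Xist remained the transcript with the largest excess in females (6.65 ± 0.22, adjusted p of 1.04e-16), with 387 ± 61.3 CPM in females (SD, n = 5) and 3.87 ± 1.23 CPM in males (n = 6). The 4 Y-linked genes were lower, with log2 fold changes from -5.61 to -5.43 (list adjusted p of 2.81e-159, and 4.34e-11 with an estimated correlation). Of the list of X-linked genes that escape inactivation, which also holds Xist, 3 of 5 members were higher (list adjusted p of 1.19e-60, and 1.05e-09 with an estimated correlation). Ugt1a2 was higher in females (4.88 ± 0.62), as was Tbr1, a T-box transcription factor gene, at 1.25 ± 0.370 CPM in females and 0.133 ± 0.0529 CPM in males (3.18 ± 0.44, adjusted p of 3.31e-04). Stmn2 (2.31 ± 0.44, adjusted p of 0.0202) and Elavl4 (2.36 ± 0.48, adjusted p of 0.031), both best known from neurons, were also higher in females. Male-high kidney genes had 0 of 8 members past the threshold over all genes and 6 lower in females when adjusted over the list alone (adjusted p of 1.21e-07, and 0.0356 with an estimated correlation). Female-high genes had 1 of 4 higher by either adjustment (adjusted p of 0.00313, adjusted p = 0.252 with an estimated correlation). For them the adjusted p was 0.054 without male cisplatin 6 (range over the alternatives 0.000238 to 0.252). Without any member past the threshold over all genes, matrix (adjusted p of 1.29e-05), endothelial (0.00254) and osmoprotection genes (0.0137) were shifted up in females, with adjusted p = 0.252, adjusted p = 0.434 and adjusted p = 0.434 with an estimated correlation. Keratins (8.06e-04), antioxidant (0.00281), injury and repair (0.0168) and interferon response genes (0.0454) were shifted down, with adjusted p = 0.252, adjusted p = 0.434, adjusted p = 0.703 and adjusted p = 0.778 with an estimated correlation. Of these 7 lists, 3 keratins were lower when adjusted over the list alone, and 0 members of the other lists passed. The other 28 tested lists had adjusted p from 0.0869 to 0.912. In edgeR's test 28 genes differed, 19 higher and 9 lower in females. That count was 127 with DESeq2, 55 with the tubule marker score as a covariate and 11 with limma-voom. Without single libraries it was 12 (male cisplatin 3), 15 (male cisplatin 4), 49 (male cisplatin 6), 13, 17, 18 and 120 (female cisplatin 1 to 4).

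Stmn2 and Elavl4 lay near the threshold under cisplatin, and their calls ended without any one of several libraries while the log2 fold change stayed between 2.05 and 2.58 for Stmn2 and between 2.16 and 2.68 for Elavl4 over all alternatives. The adjusted p of Stmn2 was 0.0547, 0.0675 and 0.0754 without male cisplatin 2, 3 and 4, 0.0582 and 0.0688 without female cisplatin 2 and 3, and 0.122 with limma-voom (range over the alternatives 0.000149 to 0.122). That of Elavl4 was 0.0615, 0.0803, 0.0941 and 0.111 without male cisplatin 1 to 4, 0.139, 0.076 and 0.0969 without female cisplatin 1 to 3, and 0.122 with limma-voom (range 0.00088 to 0.139). The call of Eif2s3x (0.64 ± 0.12, adjusted p of 0.02) was lost without male cisplatin 3 (0.0592), female cisplatin 1 (0.0539) or female cisplatin 2 (0.076) and with cisplatin libraries fitted alone (0.235, range 0.000486 to 0.235). For Kdm6a (1.04 ± 0.14, adjusted p of 3.31e-04) it was 0.0608 with cisplatin libraries fitted alone (range 2.65e-08 to 0.0608).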

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

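The tests of the erythroid transcripts, of the smaller number of female libraries and of other splits for the female contrast were chosen after the results were seen.

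Erythroid transcripts were lower after cisplatin in both sexes, and the summed hemoglobin level was at most 14.7 CPM in 11 cisplatin libraries and 95.4 to 380.7 CPM in 13 saline libraries, with no overlap within a sex. The scaling of the libraries is argued against, since the median erythroid log2 fold change closest to 0 over 3 normalizations and both sexes was -4.51. Less blood in the tissue cannot be told apart from fewer such transcripts in the same amount of blood: lymphocyte markers, which blood also carries, had medians of 0.12 in males and -0.14 in females, but with 5 tested genes, SDs of 0.70 and 1.34 and resident lymphocytes as another source. Female saline 1 stood apart in these markers, with a list score of 2.90 against 1.17 to 1.44 in the other 6 female saline libraries. Cisplatin treatment may have lowered these transcripts, which is a hypothesis that the separation of the groups does not prove.

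Fewer genes were called in females (49) than in males (3731), while the interaction test called 0 genes in edgeR (772 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom). The smaller number of female cisplatin libraries is argued against as the whole cause, because with 5 of the 6 male cisplatin libraries at least 2554 genes were called. A wider spread between female cisplatin libraries over all tested genes is argued against, since the median SD of log2 CPM was 0.776 of that in male cisplatin libraries (0.702 to 0.982 with 1 library left out). Between saline libraries the female SD was 1.23 times the male one. A median over all tested genes does not test the spread of the response itself, so a wider spread there stays open. The SD of the response score given next was 0.354 in females and 0.335 in males. The female count was 139 without female cisplatin 3 and 21 without female cisplatin 4. A weaker response in females cannot be told apart from chance: a response score over 4881 genes called in the average of both sexes was 0.485 ± 0.354 in females (SD, n = 5) and 0.783 ± 0.335 in males (SD, n = 6), with an exact two-sided permutation p of 0.177. The scores were 0.233, 0.243, 0.216, 0.955 and 0.777 in female cisplatin 1 to 5, and 0.217 in male cisplatin 6 against 0.532 to 1.05 in male cisplatin 1 to 5.

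Chance was tested by splitting the libraries in 99 other ways. It is unlikely for the male count (3731, highest other 3121, 1 of 100 splits as large) and sex under saline (34, highest other 8, 1 of 100). It is also unlikely for the female count (49, highest other 84, 2 of 100). The 99 other splits do not exclude it for these counts. For the genes shared by both sexes (46, highest other 0, 1 of 100) the splits say little about the overlap itself. When each sex was split by itself, 94 of 99 other splits in males and 96 of 99 in females called 0 genes. A shared count of 0 was thus nearly fixed. Chance cannot be excluded for sex under cisplatin (28, highest other 4578, 12 of 100), where the large counts of other splits point to a structure of the cisplatin libraries beyond sex. This concerns the count as a whole: within it Xist was at least 307.7 CPM in female and at most 5.61 CPM in male cisplatin libraries, and the Y-linked list passed with an estimated correlation (4.34e-11). For the interaction the real count of 0 makes all 100 splits at least as large, so the splits say nothing about chance there (highest other 920).

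In 14 gene lists the cisplatin response differed between females and males by the camera test of the interaction with its preset correlation, and in 0 of them with an estimated correlation (adjusted p from 0.721 to 0.733). The adjusted p was 0.000333 for tubular injury and repair, 1.83e-05 for the interferon response, 0.000267 for fibroblast and extracellular matrix, 0.00546 for female-high kidney genes, 0.0107 for immediate early genes, 0.0123 for oxidative phosphorylation and 0.0124 for urothelial markers. It was 0.0141 for keratins, 0.0272 for macrophage markers, 0.0292 for endothelial markers, 0.0307 each for intercalated cell markers, erythroid markers and fatty acid oxidation, and 0.0477 for thick ascending limb markers.

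Single libraries lay far from the rest of their group in 35 of 440 group values tested (8.0%), 7 of them in male cisplatin 5 and 4 each in female saline 5 and female saline 7. Chance gives about 5%, or 1 in 20 groups, only for independent and normally distributed values. The CPM values were not on a log scale, and the summed hemoglobin level is the sum of 4 genes also tested, so 5% is no firm reference. Each value below is the gap to the nearest other library divided by the group's range. Male cisplatin 5 was highest for the summed hemoglobin level (0.825), Hbb-bt (0.761), Hbb-bs (0.733), Hba-a1 (0.798), Hba-a2 (0.681), the share of ribosomal protein genes (0.719; 5.73% against 2.37% to 3.31%) and Fhit (0.646). Female saline 5 was highest for Kel (0.653), Hbb-bt (0.577), Mt2 (0.627) and Ccn2 (0.738). Female saline 7 was highest for Slco1a1 (0.598), Cyp2j13 (0.597), Slc7a13 (0.584) and Acsm3 (0.796), and female cisplatin 1 for Slco1a1 (0.718) and Cyp2j13 (1.0), while it was lowest for Ren1 (0.713). Female cisplatin 4 was highest for Lgals3 (0.855) and Clu (0.773). Male cisplatin 2 was highest for Trpv5 (0.628) and Cuzd1 (0.765), male cisplatin 4 for Slc7a12 (0.712) and male cisplatin 6 for Hspa4l (0.77). Male saline 6 was highest for Kel (0.659) and Elavl4 (0.643), male saline 1 for Dpyd (0.705), and male saline 2 lowest for the scores of intercalated cell (0.786) and thick ascending limb markers (0.648). Female saline 1 was highest for Trpv5 (0.607), female saline 4 for Trpv6 (0.589) and female saline 2 for the first principal component (0.671), and female saline 6 was lowest for Xist (0.651). Male saline 3 (0.721) and female saline 3 (0.771) were the lowest of their groups for Ddx3x.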

How the results depend on the processing

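The alternative without 3 libraries of divergent composition (male cisplatin 5, female saline 1 and female saline 6) was chosen after the data were seen, and all other alternatives before. None of the results reversed in direction while past the threshold. Scaling by DESeq2 size factors or total counts and the CPM filter left every count of genes within 1.5 times of its reported value, and the interaction count was 0 under every alternative. The male count left that range with the tubule marker score as a covariate (1563) and with only the compared groups fitted (2402). For the female contrast the count was 85 with no filter, 241 with DESeq2, 12 with limma-voom, 28 with the tubule marker score, 20 with only the compared groups and 32 without the 3 libraries. For sex under saline it was 58 with DESeq2 and 57 with limma-voom, and for sex under cisplatin 127 with DESeq2, 11 with limma-voom and 55 with the tubule marker score. For genes shared by both sexes it was 80 with no filter, 194 with DESeq2, 12 with limma-voom, 27 with the tubule marker score, 18 with each sex fitted alone and 29 without the 3 libraries. The correlation of fold changes was 0.175 with no filter. With 1 library left out, the count ranged from 2554 to 5268 in males, 21 to 139 in females, 21 to 41 for sex under saline, 12 to 120 for sex under cisplatin and 19 to 122 for both sexes, and the correlation from 0.596 to 0.746. The cause was not tested.

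With the replicate number as a block the female count was 16 and the count for both sexes 13. The numbers do not pair the libraries, so the block uses degrees of freedom without a shared source, and a call lost under it is not read as a weaker effect. The tubule marker score was measured in the same libraries after treatment and is built from members of lists tested here. A call lost with it therefore does not separate tubule tissue in the samples from an effect of cisplatin or sex on these markers.

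Of 43 list tests described, 23 lost their call with an estimated correlation, 13 with fry and 7 with the tubule marker score. These 43 include lists that had not passed and so had no call to lose. Of 209 results for named genes, which also include genes without a call, 33 lost theirs with the tubule marker score, 24 with limma-voom and 0 with DESeq2. Depth limits Havcr1, which had too few counts to be tested, and genes near 1 CPM such as Kel and Tbr1.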

Other observations

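The test of long genes without 3 libraries was chosen after the result was seen, and the other tests of long genes before theirs, but on a pattern noticed in the same data.

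Kel, Trpv5 and Trpv6 lie beside each other on chromosome 6, and the genes around them were looked up after their values were seen. Between Trpv5 and Kel, Llcfc1 had log2 fold changes of 5.38 in males and 3.31 in females, and Ephb6, on the other side of Trpv6, 1.06 (adjusted p of 0.000386) and 0.51 (adjusted p of 0.185). The outer neighbours Gstk1 (0.07 and 0.04) and Tmem139 (-0.17 and -0.27) did not pass in either sex, and Mgam was lower (-1.23, and -1.03 with an adjusted p of 0.265 in females). Llcfc1 reached 0.863 CPM and Kel 1.24 CPM in male cisplatin libraries against 65.5 CPM for Trpv6. Without a stated strand, reads that run past the end of one gene into the next cannot be separated.

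Genes of long genomic span were lower after cisplatin. The median log2 fold change of 765 genes spanning at least 200 kb was -0.21 in males and -0.18 in females, against 0.14 and 0.06 for 9348 genes of under 20 kb, and per library the long-minus-short difference was lower in cisplatin than in saline by -0.35 in males (exact two-sided permutation p of 0.00216, the smallest possible) and -0.24 in females (exact p of 0.0202). As the whole cause, exon length is argued against by a difference below 0 in all 4 of its quartiles in both sexes (closest to 0 at -0.10), GC content by -0.24 or lower averaged over its quartiles, loss of stromal and endothelial cells by -0.21 or lower with both list scores as covariates, and the 3 libraries of divergent composition by -0.28 in males (exact p of 0.00216) and -0.29 in females (exact p of 0.0159) without them. The libraries with the highest shares of ribosomal protein genes were also the lowest. Male cisplatin 5 (5.73%) was at -0.69, male cisplatin 3 (3.31%) at -0.50, and female cisplatin 4 and 5 (3.92% and 3.59%) at -0.37 and -0.35. Female saline 6 (-0.27), with the highest share of the saline libraries (2.64%), lay below female cisplatin 1 to 3 (-0.04, -0.25 and -0.21). How far this share accounts for the difference was not tested. A candidate explanation is that cisplatin, which binds DNA, lowers long transcripts more than short ones, a hypothesis found and tested on the same libraries, while RNA quality and the share of other cell types were not tested and remain open.

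The 4 Y-linked genes together were at 1.06% to 3.38% of the male mean in female saline libraries and at 1.55% to 3.51% in female cisplatin libraries. Female saline 5, 6 and 7 and female cisplatin 1 had the highest values (2.90%, 3.38%, 3.31% and 3.51%). Female saline 7 and female cisplatin 1 were also the highest of their groups for the male-high genes Slco1a1 (0.409 and 0.173 CPM) and Cyp2j13 (0.286 and 0.216 CPM). Carry-over of reads between libraries and reads shared with X-linked homologs were not tested as the origin of these values. Xist was at 0.27% to 0.64% of the female mean in male saline and at 0.54% to 1.45% in male cisplatin libraries. Mitochondrial genes took a mean of 5.54% of counts in male saline, 4.44% in male cisplatin, 4.67% in female saline and 5.05% in female cisplatin libraries.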
